A study of Mus musculus with 2 samples.

How the data were processed

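Histone H3 acetylated at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in limb tissue of mouse embryos at embryonic day 14.5. Per the labels, there was 1 group of 2 biological replicates, pools of 24 and 34 embryos of mixed sex, with a size range of 300 to 500 bp. Each replicate was called against its own control alignment, and the controls of the replicates were different files. With 1 tissue, 1 stage and no second condition, no comparison between conditions was made.

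The deposited files were 4 peak lists on the mm10 assembly, and no reads were used here. The authors called a list on each replicate's filtered alignments with its control, a pooled list on both replicates with both controls, and a replicated list derived from the pooled list and both replicates' own lists. The caller, its version and the rule for the replicated list were not given in the sources used here. Column 7 of each deposited list holds the authors' signal value per peak, an enrichment over the control whose scale was not stated further, and it is called the enrichment value here. Columns 8 and 9 hold the authors' −log10 p and −log10 q per peak, and column 10 the distance of the summit from the peak start in bp, as deposited. Enrichment values were used to describe and rank peaks within a list, to set the medians of the lists side by side and for the rank correlation between the replicates, q-values as a stricter filter, and summits to centre the motif windows. A lowest −log10 p of 2.00 to 2.02 in the 4 lists was the only sign of a cutoff in the values. The number of reads behind each list was unknown, so no interval that needs depth was given for any signal value. Confidence intervals on shares of peaks were 95% Wilson intervals and cover counting error only.

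Peaks on the 21 assembled chromosomes were compared with the GRCm38 genome sequence and the GENCODE vM21 annotation. A peak was counted as shared if at least 1 bp was overlapped by a peak of the other list. Random placement moved one list 100 times to random positions on the same chromosomes, outside assembly gaps of 1 kb or more. Peaks were classed by midpoint as within 1 kb of an annotated transcription start site (TSS) of any gene, exonic, intronic or intergenic, in that order. A promoter was called marked if a replicated peak overlapped the 1 kb either side of any TSS of a protein-coding transcript of the gene. Distal peaks, those not overlapping the 1 kb either side of any TSS, were assigned to the nearest protein-coding TSS within 500 kb. Domains were made by joining replicated peaks across gaps of up to 12.5 kb and were ranked by the summed length of their peaks.

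For 22 gene lists, the share of marked promoters was compared with all other protein-coding genes by 2-sided Fisher's exact tests. The mean number of distal peaks per gene was compared with 10000 random gene lists of the same size, matched in deciles on the distance between neighbouring TSSs, by a 2-sided permutation p. For 27 consensus motifs, the 200 bp either side of each peak summit were searched on both strands. They were compared by 2-sided Fisher's exact tests with windows of like GC content, in bins of 2 percentage points, taken 5 to 50 kb away and outside all pooled peaks. The p-values of the lists and of the motifs were adjusted by the Benjamini-Hochberg method over the lists or over the motifs, with a threshold of 0.05. Single tests of explanations and hypotheses in the closing part were not adjusted. Genes, peaks and windows of the same libraries are not independent replicates, so these tests describe these libraries.

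The gene lists, the motifs, the tests, the thresholds and most alternative settings were chosen before the data were examined. For each list, all members were named if it had 12 or fewer members or was a Hox list. From longer lists, the 3 marked members with the highest enrichment value in the pooled list and the first 3 unmarked members in alphabetical order were named. The 10 widest domains, the 10 genes with the most distal peaks, the 10 promoters with the highest enrichment value and the 3 highest peaks unique to each replicate were named too. Of the motifs past the threshold, the 5 highest and the 3 lowest odds ratios were named. Any gene, peak or motif named beyond that rule was chosen after its values were seen.

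Alternative settings were each replicate's own list in place of the replicated one, the pooled list, q of at most 0.01, other overlap rules, other TSS windows and TSS sets, other assignment distances, lists matched on promoter CpG content or not matched, other stitching, windows of 500 bp and no GC matching. Added after seeing the data were a list of only those replicated peaks that were overlapped in both replicates' own lists, a list test on genes with no other coding TSS within 2 kb, and motif windows with at most 20% soft-masked (repeat) bases. A value without a test was read as moved if it left its 95% interval, or, for Hox coverage and peaks per Mb, if it changed by more than the SD of both replicates' own lists. Counts were read as moved if they changed by more than 1.5 times.

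The code was tested on simulated data before use. A simulated overlap of 50.3% over 70970 peaks was recovered as 50.3%, with 0 peaks of difference from bedtools. Shared peaks in it were exact copies, and moved peaks that overlapped the original list were removed, so partial overlap was not simulated. Simulated gene lists were called in 98% of cases with 90% of members marked, in 43% with 70% marked, and in 4.5% when unchanged. Lists with 3 times the distal peaks were called in 50% of cases, and unchanged lists in 4%. A planted excess of 5 percentage points of TEAD matches over 10314 windows was recovered as 4.64 points, and 0 other motifs were called. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and bedtools 2.31.1 were used. Peaks on sequences outside the 21 chromosomes were left out of all comparisons.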

Results

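H3K27ac peaks were mapped in the embryonic mouse limb at day 14.5, a stage with cartilage templates of the skeleton, differentiating muscle and separating digits. The replicate lists held 71847 peaks (replicate 1) and 87146 peaks (replicate 2), the pooled list 88670 and the replicated list 38729. They covered 1.13%, 1.37%, 1.67% and 1.21% of the genome. Median peak lengths were 264, 261, 306 and 604 bp, and median enrichment values 3.43, 3.64, 3.23 and 4.45. A q above 0.01 was carried by 37.1% of the peaks of replicate 1, 32.5% of replicate 2, 21.5% of the pooled list and 1.45% of the replicated list.

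The strongest H3K27ac of the limb recurred in both pools of embryos, while weak peaks often did not. Of the replicate 1 peaks, 39687 of 71841 (55.2%, 95% CI 54.9 to 55.6) overlapped a replicate 2 peak, against a mean of 3.05% after random placement. Of the replicate 2 peaks, 38197 of 87136 (43.8%, 43.5 to 44.2) overlapped a replicate 1 peak, against 2.33%. In the quartile of replicate 1 with the highest enrichment values 95.03% of peaks were shared, and in the lowest 30.9%. The same quartiles of replicate 2 gave 88.7% and 20.8%. Peaks at a TSS were shared more often (79.4% of replicate 1 and 68.1% of replicate 2) than distal peaks (44.8% and 34.5%). Shared peaks were also longer, with a median of 333 bp against 207 bp for the unshared distal peaks of replicate 1. Over 34280 pairs of overlapping peaks the enrichment values of the replicates correlated with a Spearman's rho of 0.679, a correlation across peaks. With a reciprocal overlap of at least 50% of both peaks required, the shared shares fell to 31.3% and 25.8%.

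**Figure D1:**
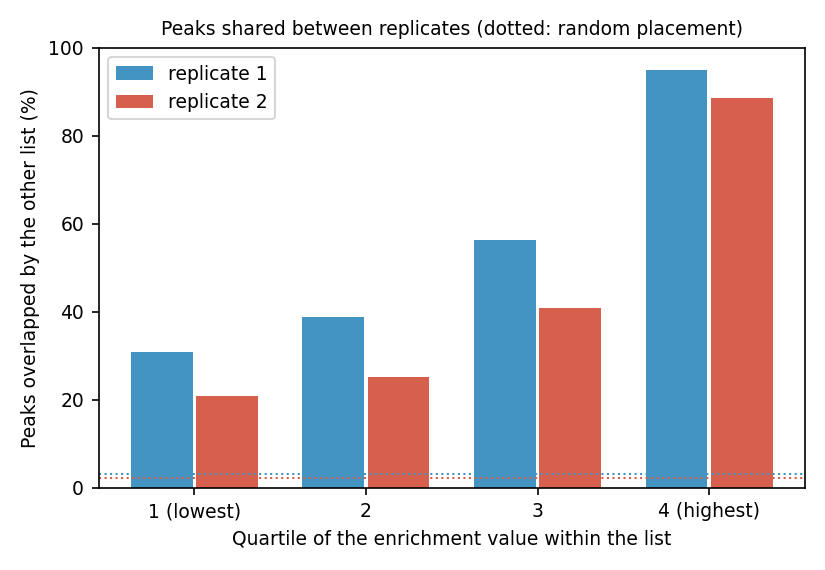
Percent of each replicate's peaks that overlapped a peak of the other replicate, by quartile of the enrichment value within each list, with dotted lines for random placement. The share was highest in the top quartile, 95.03% for replicate 1 and 88.7% for replicate 2.

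The highest peaks without a counterpart in the other replicate were all present in the pooled list. In replicate 1 they were a 348-bp peak at a TSS at chr6:47781815–47782162 (enrichment value 8.43), a 427-bp peak at the promoter of Camk2g, a calcium/calmodulin-dependent kinase subunit, at chr14:20765600–20766026 (7.81), and a 517-bp intergenic peak at chr14:76977679–76978195 (7.55), 58.1 kb from the TSS of Lacc1. In replicate 2 they were a 630-bp peak at a TSS at chr19:5848586–5849215 (9.50), a 609-bp intronic peak at chr6:101319382–101319990 (9.27), 58.2 kb from the TSS of Pdzrn3, and a 469-bp peak at the promoter of Btbd11 at chr10:85386803–85387271 (9.12). An exonic peak nearest to Nln and a peak at the promoter of Wscd2 tied with the Btbd11 peak at 9.12.

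The replicated list kept 38724 of the 88660 pooled peaks (43.7%), with 98.7% of the highest quartile of enrichment values and 5.87% of the lowest. It kept 66.2% of the pooled peaks near a TSS and 35.4% of the distal ones. All 32399 pooled peaks overlapped over at least 50% of the shorter peak in both replicates' own lists were kept. A further 6092 kept peaks were not overlapped in both own lists.

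Promoters took up a larger part of limb H3K27ac than their share of the genome, and most other peaks lay far from any coding gene's start. Of the replicated peaks, 14826 (38.3%, 95% CI 37.8 to 38.8) were centred within 1 kb of a TSS, 6.03 times the 6.35% given by random placement. These peaks were longer (median 780 bp) and stronger (median enrichment value 6.66) than intronic ones (528 bp and 3.93). Introns held 13513 peaks (34.9%, random placement 40.3%), intergenic sequence 9161 (23.7%, 0.473 times random placement) and exons 1224 (3.16%, random 3.39%). The 22969 distal peaks (59.3%) lay at a median of 34.4 kb from the nearest coding TSS. The TSS share was 25.2% in the pooled list, 28.7% in replicate 1 alone and 26.1% in replicate 2 alone.

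A marked promoter was found at 10721 of 21938 protein-coding genes (48.9%). None of the 10 promoters with the highest enrichment values belonged to a gene of the tissue lists. They were Tnrc18 (79.1, with 11288 bp of peak), Klf7 (75.3), Erbin (72.9), Epc1 (71.0), Arrdc3 (69.8), Kansl1 (69.0), Bicral (68.8), the histone methyltransferase gene Kmt5b (68.4), Zc3h4 (67.4) and Gabpb1 (66.6).

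Regulators of limb mesenchyme, cartilage genes, tendon and joint genes and the HoxA and HoxD clusters were marked more often than other genes, of which 48.8% to 48.9% were marked. Among the limb mesenchyme and outgrowth regulators 26 of 28 promoters were marked (92.9%, odds ratio 13.6, adjusted p 7.71e-06). The highest enrichment values were at the zinc finger homeobox genes Zfhx4 (47.9, chr3:5217668–5224224) and Zfhx3 (46.6, chr8:108701068–108708840) and at Gli3 (45.5, chr13:15461792–15465790), a transcription factor of hedgehog signalling that limits digit number. The only unmarked members were Sall3 and Sall4. Of the cartilage genes 21 of 26 were marked (80.8%, odds ratio 4.40, adjusted p 0.00229), led by Trps1 (24.98), Sox9, the master regulator of chondrocytes (20.6, chr11:112780822–112785920), and the parathyroid hormone receptor Pth1r (18.4). Col10a1, a collagen of hypertrophic chondrocytes, Comp and Epyc were unmarked. Of the tendon, joint and connective tissue genes 17 of 20 were marked (85%, odds ratio 5.94, adjusted p 0.00229), with Pdgfra (43.1), Tcf4 (34.6) and Col3a1 (24.5) the highest, and with Prg4, Thbs4 and Tnmd, genes of the joint surface and of mature tendon, unmarked. Tcf4 entered this list by its symbol, as the gene at chr18:69344482–69349440, and whether it belongs among connective tissue genes was not examined. The HoxA and HoxD list gave the same count, 17 of 20 marked, but against lists matched on promoter CpG content it was not past the threshold (adjusted p 0.442). All 26 housekeeping genes were marked (adjusted p 8.91e-08), with Ywhaz (44.7), Eef1a1 (33.2) and Actb (33.1) the highest.

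Genes that set forelimb or hindlimb identity were marked on both sides, and the list was not past the threshold against other genes (6 of 9 marked, 66.7%, adjusted p 0.367). The forelimb gene Tbx5 (21.3) lay under a 15377-bp peak at chr5:119828659–119844035, one of the widest of the list, and the hindlimb genes Pitx1 (16.3) and Tbx4 (16.2) were marked at chr13:55829802–55832708 and chr11:85887845–85892261. Hoxc11 (6.48), Hoxc10 (5.46) and Hoxc9 (4.22) were marked, and Isl1, Hoxc4 and Hoxc5 were not.

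Signals of the apical ridge and the polarizing region, which drive early limb bud outgrowth, were marked at 6 of 16 promoters (37.5%, adjusted p 0.478). The highest were 2 targets of hedgehog signalling, Ptch1 (37.9) and Gli1 (19.1), and the fibroblast growth factor target Dusp6 (20.1). The ligand genes Fgf17, Fgf4 and Fgf8 were unmarked, while the ligand genes Fgf10 (6.58) and Fgf9 (4.66), chosen after their values were seen, were marked. The share was 56.2% in the pooled list and 62.5% in replicate 1 alone, neither past the threshold.

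Bone genes were marked at 5 of 18 promoters (27.8%, adjusted p 0.126), with the collagen genes Col1a2 (17.0) and Col1a1 (16.9) and the osteoblast regulator Satb2 (10.5) the highest. Alpl, Bglap and Bglap2, genes of mineralizing osteoblasts, were unmarked. Alpl held a peak in the pooled list (2.63), replicate 1 (2.81) and replicate 2 (2.87), while Bglap and Bglap2 held none in these lists. When only the 5′ end of the gene record was used as promoter, 16.7% of the bone list was marked (adjusted p 0.0231). Replicate 2 alone, in which 11809 of 21938 promoters held a peak, gave 55.6%, not past the threshold. Skeletal muscle genes were marked at 10 of 27 promoters (37.0%, adjusted p 0.290). The muscle regulators Eya1 (11.4), Mef2c (11.4) and Six1 (8.89) were the highest, and the actin genes Acta1 and Actc1 and the acetylcholine receptor gene Chrna1 were unmarked. Of other members, chosen after their values were seen, Six4 (8.83) and Myog (3.85) were marked. Myod1, Myf5, Myf6, Pax3 and Pax7 held no peak in the pooled list or either replicate's own list. Lbx1 was unmarked but held a peak in the pooled list (3.04) and replicate 2 (4.18). Replicate 2 alone gave 59.3% for muscle (adjusted p 0.856).

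Epidermal genes were marked less often than other genes, at 4 of 24 promoters (16.7%, odds ratio 0.209, adjusted p 0.00276). Marked were the suprabasal keratin gene Krt10 (20.8), the regulators Tfap2a (10.5) and Grhl2 (6.07), and Perp (4.45), the last chosen after its value was seen. The cell adhesion genes Cdh1, Dsc3 and Dsg3 were unmarked. This call rested on the replicated list, since 33.3% were marked in the pooled list (adjusted p 0.0549) and 29.2% in replicate 1 alone (adjusted p 0.0595). In replicate 2 alone 54.2% were marked, not past the threshold, in a list with a peak at 11809 of 21938 promoters. Endothelial genes were marked at 7 of 18 promoters (38.9%, adjusted p 0.483), with the transcription factor genes Fli1 (17.7) and Erg (8.56) and the adhesion gene Pecam1 (6.27) the highest and Cdh5, Cldn5 and Emcn unmarked. In the pooled list 83.3% of the endothelial promoters held a peak (adjusted p 0.0306), and in replicate 2 alone 77.8% (adjusted p 0.0826).

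Genes of blood cells were marked less often than other genes. Of the erythroid genes 3 of 16 were marked (18.8%, odds ratio 0.241, adjusted p 0.0319), the transferrin receptor Tfrc (10.1), Ank1 (3.76) and Nfe2 (3.20), while Alas2, Epb42 and Epor were not. Of the macrophage and leukocyte genes only Aif1 (3.88) was marked (1 of 16, odds ratio 0.0697, adjusted p 0.00132), and Adgre1, C1qa and C1qb, markers of macrophages, were not. In replicate 1 alone 18.8% of the leukocyte promoters held a peak. In the pooled list 25% of the leukocyte and 25% of the erythroid promoters did (adjusted p 0.0319 for each). Against lists matched on promoter CpG content neither call held (adjusted p 0.906 for erythroid and 0.415 for leukocyte genes), and the erythroid call ended on genes without a neighbouring coding TSS within 2 kb (adjusted p 0.0672). Schwann cell and melanoblast genes were marked at 4 of 15 promoters (26.7%, adjusted p 0.146). The peaks at Pmel (20.04) and Mpz (8.33) also lay at the promoters of Cdk2 and Sdhc, and Erbb3 (6.48) followed, while Cdh19, Dct and Fabp7 were unmarked.

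Promoters specific to other organs were nearly empty. None of 20 hepatocyte genes (adjusted p 1.14e-05), 16 gut and pancreas genes (adjusted p 0.000142) or 12 pluripotency genes (adjusted p 0.00132) was marked. These included Afp, Ahsg and Alb of the liver, Cdh17, Cdx1 and Cdx2 of the gut, and all of Pou5f1, Nanog, Zfp42, Esrrb, Tfcp2l1, Dppa5a, Tdgf1, Dppa4, Dppa2, Fgf5, Utf1 and Tdh. Of 20 genes of central nervous system neurons only Elavl4 (4.048) was marked (odds ratio 0.0550, adjusted p 0.000157), with Dcx, Elavl3 and Eomes unmarked. Of 16 germ cell genes only Dazl (3.30) was marked (odds ratio 0.0697, adjusted p 0.00132), with Ddx4, Dppa3 and Gdf9 unmarked, and with only the 5′ end of the gene record the adjusted p was 0.0537. Of 16 cardiomyocyte genes 2 were marked (odds ratio 0.149, adjusted p 0.00678), Myl3 (18.4), under the same 2739-bp peak at chr9:110741601–110744339 as Pth1r, and Myh7 (3.64), with Gata4, Hcn4 and Mybpc3 unmarked. Among 1135 olfactory receptor genes 1 was marked (0.0881%, against 51.5% of other genes), Olfr1342, while Olfr1, Olfr10 and Olfr1000 were not. In single replicates 0% to 18.8% of the promoters of each of these 6 organ lists held a peak and 0.264% of olfactory receptors, and all 7 calls held. In the pooled list the highest share of the 6 was 25%, for cardiomyocyte genes (adjusted p 0.0319). In all, 5 of the 22 lists were marked more often than other genes and 10 less often.

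**Figure D2:**
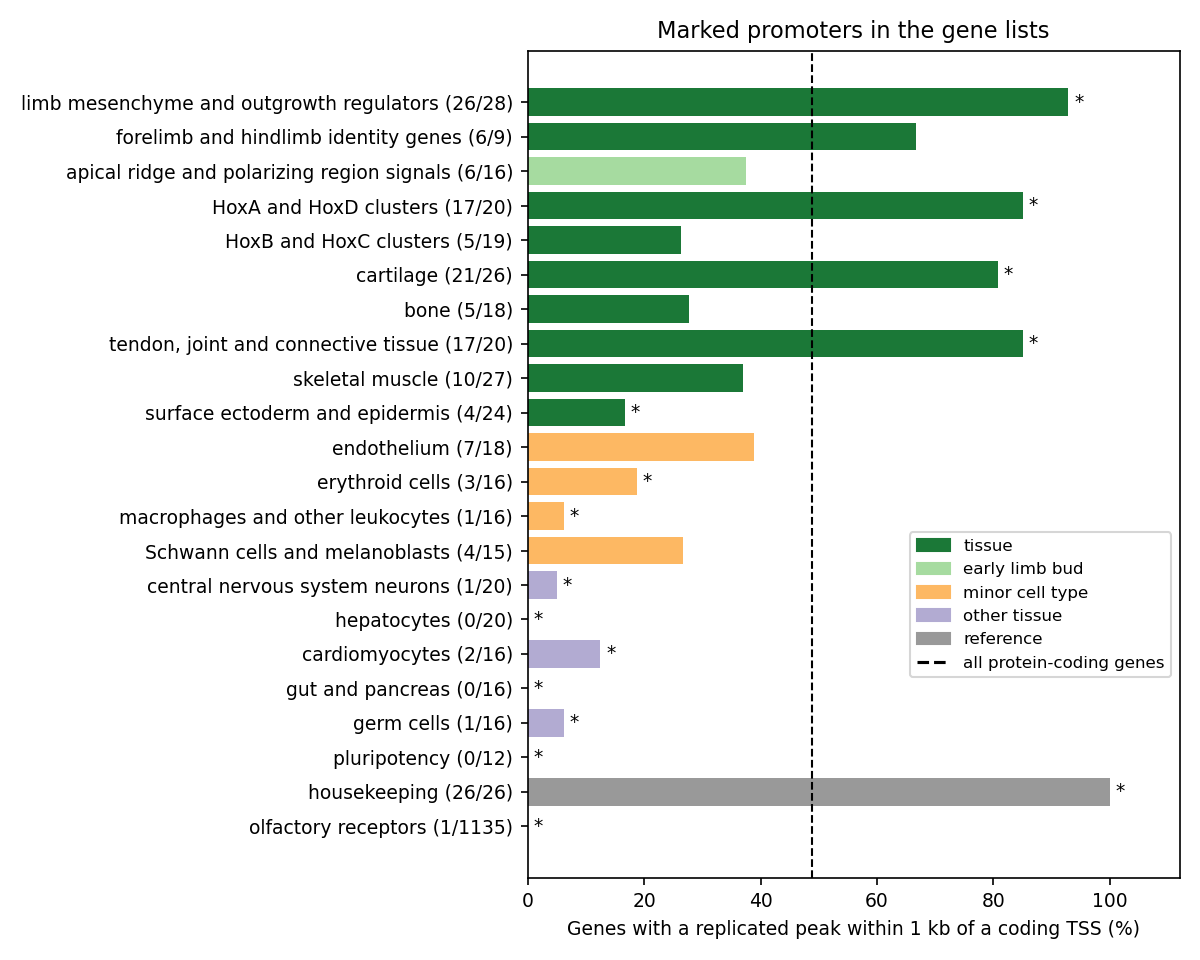
Percent of promoters with a replicated H3K27ac peak for each gene list, with an asterisk for an adjusted p under 0.05 and a dashed line for all protein-coding genes (48.9%). Limb mesenchyme regulators reached 92.9%, and hepatocyte, gut and pluripotency genes 0%.

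Distal peaks gathered around genes of the limb mesenchyme and of cartilage. The limb mesenchyme list had 295 distal peaks, 10.5 per gene and 3.57 times matched random lists (adjusted permutation p 0.0022, with the unadjusted p at 0.0002, the smallest that 10000 lists can give), with 70 at Zfhx3, 30 at Gli3 and 14 at Zfhx4. Cartilage genes had 6.58 per gene, 3.96 times random lists (adjusted permutation p 0.00587), with 16 at Sox9, 9 at Trps1 and 1 at Pth1r. Tendon, joint and connective tissue genes had 6 per gene (2.88 times random lists, adjusted permutation p 0.0634), with 40 of the 120 peaks at Tcf4, 17 at Col3a1 and 0 at Pdgfra. The list was not tested without Tcf4. This list was past the threshold in replicate 2 alone (17.4 per gene, adjusted permutation p 0.0114), in replicate 1 alone (12.2, 0.0407), in the pooled list (17.2, 0.0167) and against unmatched random lists (0.0055). The forelimb and hindlimb identity genes had 5.22 per gene (3.58 times, adjusted permutation p 0.103), of which 18 were at Tbx5, 16 at Tbx4 and 6 at Pitx1. Fewer distal peaks than in random lists were found at olfactory receptors (0.0291 per gene, adjusted permutation p 0.0022) and central nervous system genes (0.4 per gene, 0.190 times, adjusted permutation p 0.0495). In replicate 1 and replicate 2 alone, which held more peaks, the means were 21.1 and 25.5 for limb mesenchyme, 13.1 and 17.2 for cartilage, 0.0670 and 0.0705 for olfactory receptors and 1.4 and 1.3 for central nervous system genes. The call for the last list was lost in replicate 1 alone (adjusted permutation p 0.0598), with q of at most 0.01 (0.0561), with assignment within 100 kb (0.0799), with a TSS window of 2.5 kb (0.0748) and without matching (0.669).

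None of the other 16 lists passed the threshold for distal peaks. Endothelial genes had 3.06 per gene, bone 2.39, Schwann cell and melanoblast genes 1.8, germ cell genes 1.25, muscle 1.19, gut and pancreas 1.06 and ridge and polarizing region signals 1. Lower means were found for leukocyte (0.875), cardiomyocyte (0.875), pluripotency (0.75), housekeeping (0.731), epidermal (0.708), HoxA and HoxD (0.5), HoxB and HoxC (0.474), erythroid (0.125) and hepatocyte genes (0.1).

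The 10 genes with the most distal peaks were the mRNA decay factor Zfp36l1 (74 distal peaks), Zmiz1 (73), the nuclear factor gene Nfib (71), Zfhx3 (70), Creb5 (62), 2010111I01Rik (59), Rad51b (59), the growth arrest gene and hedgehog co-receptor Gas1 (53), Dnm3 (48) and Zfp521 (44). Rad51b and Zfp36l1 are neighbours on the genome. In all, 6106 genes had at least 1 of the 22743 assigned distal peaks and 512 had at least 10. Of genes with a marked promoter 39.1% had a distal peak, and of the others 17.1%.

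The HoxA and HoxD clusters, which pattern the limb from shoulder to digits, carried broad H3K27ac toward their 5′ ends, while HoxC was covered at some gene starts and HoxB carried little. HoxA (chr6:52155590–52260880) was covered over 44.4% of its length by 23 peaks and HoxD (chr2:74668310–74765142) over 32.8% by 10 peaks. HoxC (chr15:102921103–103036852) was covered over 9.79% and HoxB (chr11:96194316–96368256) over 1.65%, a share that was 2.77% in the pooled list. The windows of 1 kb either side of the gene start were fully covered at Hoxa7, Hoxa9, Hoxa11, Hoxa13 and at Hoxd9, Hoxd10, Hoxd11, Hoxd12 and Hoxd13, and 94.1% covered at Hoxa10. Coverage was 80.4% at Hoxa3, 20.8% at Hoxa4, 18.4% at Hoxa1, 13.9% at Hoxa6 and 3.95% at Hoxa5, and 55.6% at Hoxd8 and 33.9% at Hoxd3. The gene record of Hoxa3 starts at chr6:52213336, between the starts of Hoxa6 (52208722) and Hoxa7 (52221854). Its value therefore describes that interval and not the 3′ part of the cluster. In HoxC it was 86.1% at Hoxc10, 55.4% at Hoxc11, 53.8% at the start of the unmarked Hoxc5 record and 44.2% at Hoxc9. In HoxB it was 0% at every gene start, including those of Hoxb2 and Hoxb3, which were marked only near other coding TSSs. The 3 unmarked members of HoxA and HoxD were Hoxa2, Hoxd1 and Hoxd4, of which the gene record of Hoxd4 starts beside that of Hoxd3 and had the same 33.9% of its window covered.

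A single 13196-bp peak at chr6:52228358–52241553 spanned the starts of Hoxa9 and Hoxa10 (34.2). The next highest enrichment values in these clusters were at Hoxa11 (24.6), Hoxa7 (24.5), Hoxd11 (24.1), Hoxd12 (23.8), Hoxd13 (20.8) and Hoxa13 (19.6), the last 2 being the genes of the digit region. Hoxa3 (14.6), Hoxd9 (12.9), Hoxd10 (12.55) and Hoxd8 (9.46) followed. The Hoxa3 peak lay between the starts of Hoxa6 and Hoxa7 and also at the promoter of Gm28308. In the HoxB and HoxC list 5 of 19 promoters were marked (26.3%, adjusted p 0.0890), namely Hoxb2 (5.46), Hoxb3 (4.25), Hoxc9, Hoxc10 and Hoxc11. Unmarked were Hoxb1, Hoxb4, Hoxb5, Hoxb6, Hoxb7, Hoxb8, Hoxb9, Hoxb13, Hoxc4, Hoxc5, Hoxc6, Hoxc8, Hoxc12 and Hoxc13. This share was past the threshold against lists matched on CpG content (adjusted p 0.0196) and with a TSS window of 500 bp (21.1%, 0.0301), but was 57.9% in replicate 2 alone (adjusted p 0.902).

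**Figure D3:**
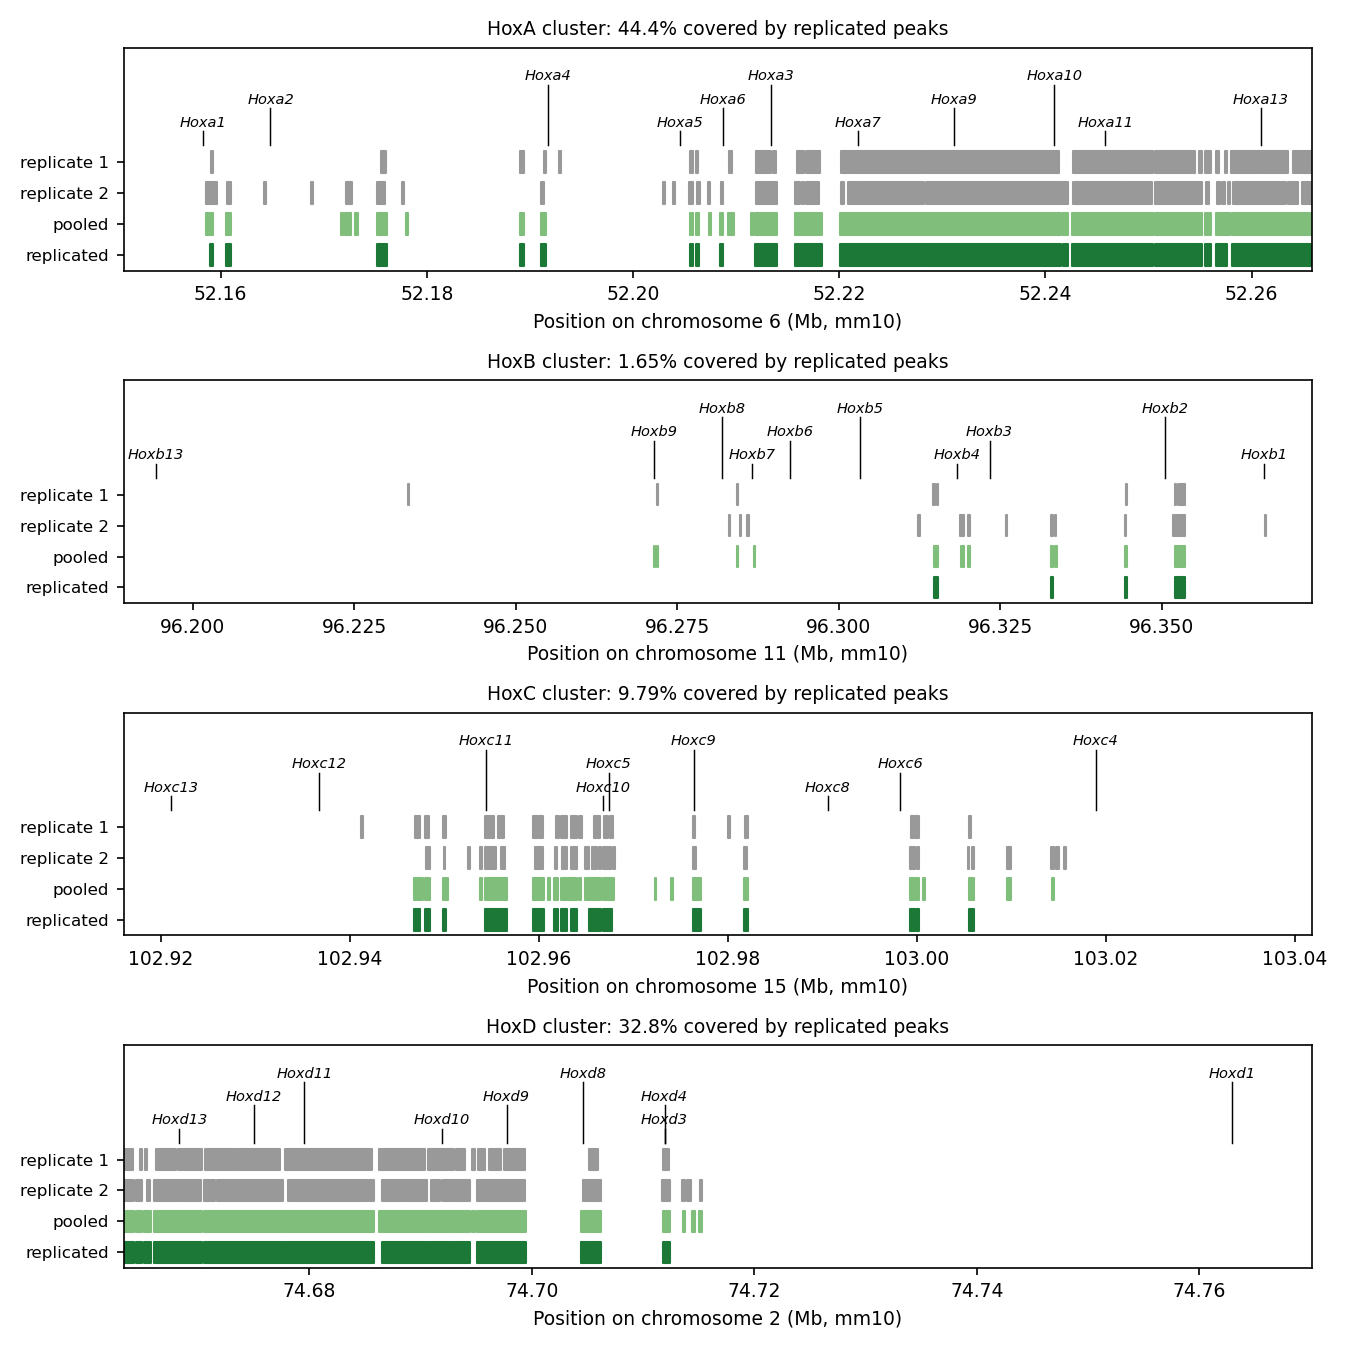
Replicated, pooled and replicate peaks along the HoxA, HoxB, HoxC and HoxD clusters, drawn to scale, with ticks at the 5′ end of each gene record. Peaks cover 44.4% of HoxA and 32.8% of HoxD but 9.79% of HoxC and 1.65% of HoxB.

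Joined across gaps, the replicated peaks formed 18936 domains, of which 10579 held 1 peak. The widest spread over the Dnm3 gene at chr1:161965087–162165598, with 85.5 kb of peak in 49 peaks and the TSSs of Pigc and 4930558K02Rik. The next, at chr6:30508992–30740320 (84.4 kb, 59 peaks), held the imprinted gene Mest with Cpa1, Cpa2, Cpa4, Cpa5, Cep41, Ssmem1 and Tmem209. The third, at chr7:142428058–142612228 (82.9 kb, 52 peaks), held the fast muscle troponin genes Tnnt3 and Tnni2 with Lsp1, Syt8 and Mrpl23, and the noncoding imprinted gene H19. HoxA with Hottip (50.2 kb, 19 peaks) came at rank 4, and HoxD with Evx2 (48.4 kb, 17 peaks) at rank 6. Between them came a domain with Nfix, Lyl1, Nacc1, Trmt1 and G430095P16Rik (chr8:84686393–84803627, 49.3 kb). The remaining 4 held Ddc and Fignl1 (chr11:11808620–11893139, 38.6 kb), 2010111I01Rik (chr13:63229319–63333999, 38.3 kb), Sept9 (chr11:117224461–117350686, 37.8 kb), and Ahdc1 and Wasf2 (chr4:133011340–133132628, 37.6 kb). The domains at Dnm3, at H19 and at HoxA stayed among the top 10 under all 7 alternative settings, and the last 4 under 1 of the 7.

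MEF2, myogenic E-box, TEAD, SOX and RUNX sequences were more frequent at distal peaks than in nearby sequence of like GC content. The highest odds ratios past the threshold among 27 motifs over 22964 distal peaks were those of MEF2, a regulator of muscle genes (0.806% of peaks against 0.444%, odds ratio 1.82, adjusted p 3.93e-06), the myogenic E-box CAGCTG (29.3% against 22.3%, 1.45, 8.63e-66), TEAD, the DNA partner of YAP (8.71% against 6.34%, 1.41, 4.76e-21), SOX (15.8% against 13.5%, 1.20, 2.69e-11) and RUNX (4.82% against 4.06%, 1.20, 0.00024). Less frequent were NFY (1.11% against 1.89%, 0.585, 3.92e-11), PITX (6.48% against 9.25%, 0.679, 2.41e-27) and T-box (1.72% against 2.33%, 0.732, 1.15e-05). In total 6 motifs were more frequent, 5 less frequent and 16 neither. Without GC matching MEF2 (odds ratio 1.09, adjusted p 0.559), RUNX (1.02, 0.691) and T-box (0.884, 0.170) were not past the threshold, and in windows with at most 20% repeat bases PITX was at 1.04 (adjusted p 0.540).

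Promoter peaks carried ZNF143, NRF1 and ETS sequences, motifs of general promoter factors, more often than nearby sequence. Of 15753 promoter peaks only the 10979 with a matched window were tested, and the others are not described by these values. The highest odds ratios were those of ZNF143 (ACTACAATTCC, 0.173% of peaks against 0.0182% of windows, odds ratio 9.51, adjusted p 0.00066), NRF1 (7.60, 4.80e-14), ETS (6.73, 1.16e-18), TCAGGTTTC, a site of the homeobox factor Six1 and its relatives (2.31, 0.00036), and SP/KLF (2.08, 9.99e-88), the last present at 22.2% of peaks against 12.04% of windows. T-box (0.560, 2.23e-07), the TWIST E-box CATATG (0.573, 1.76e-14) and PITX (0.759, 2.35e-06) were the lowest, and 6 motifs were more and 5 less frequent. No test compared promoter with distal odds ratios. The ZNF143 value rested on 19 peaks and was 14.5 in replicate 1 alone and 32.1 in replicate 2 alone. NRF1 was at 5.55 and 4.23, ETS at 4.22 and 5.60, and TCAGGTTTC at 1.497 and 1.48 in the same lists. ETS was above NRF1 in replicate 2 alone, in the pooled list (7.33 against 4.83), with q of at most 0.01 (7.43 against 3.88), with windows of 500 bp (9.27 against 8.09) and in low-repeat windows (5.17 against 4.53), and above ZNF143 in the pooled list (7.26). Without GC matching NRF1 was at 42.7, SP/KLF at 17.6, ETS at 8.68 and ZNF143 at 4.40, so the order of these motifs depended on the setting. The TCAGGTTTC site was not past the threshold with q of at most 0.01 (1.48, adjusted p 0.0812), without GC matching (1.04, 0.871) or in windows with at most 20% repeat bases (1.40, 0.181). PITX turned to 1.30 in the last of these.

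**Figure D4:**
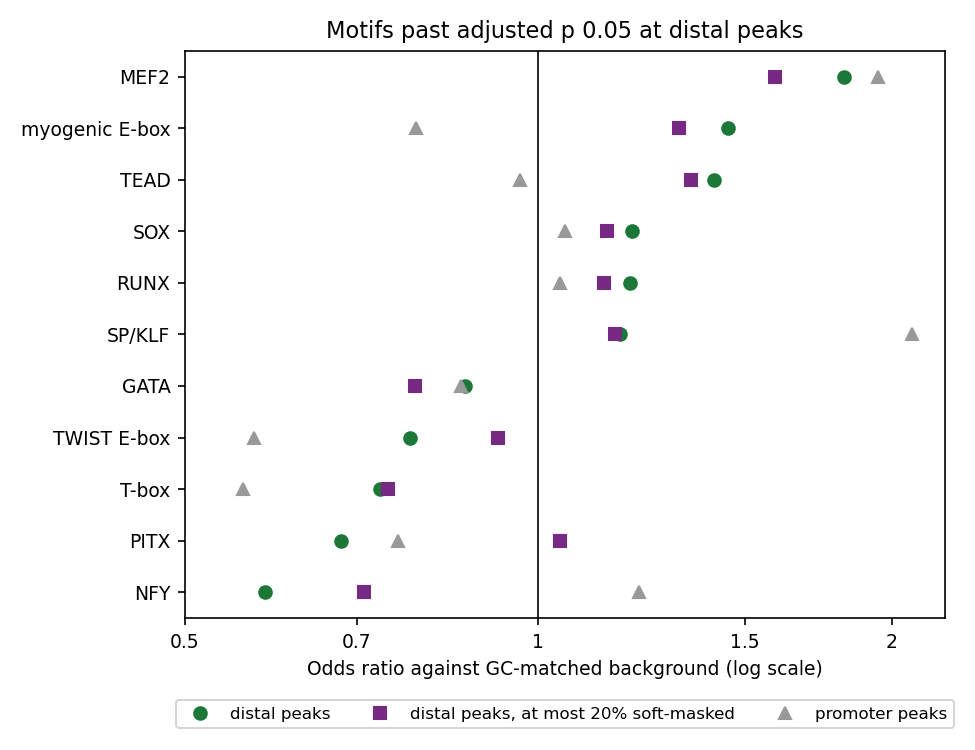
Odds ratio of each motif past the threshold at distal peaks, shown for distal peaks, for distal peaks with at most 20% soft-masked bases and for promoter peaks, each against windows of like GC content, on a log axis. Among the motifs drawn MEF2 is highest at distal peaks (1.82) and SP/KLF at promoter peaks (2.08). ZNF143, NRF1 and ETS were not past the threshold at distal peaks and are not drawn.

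The X chromosome carried fewer H3K27ac peaks than any autosome, with 735 replicated peaks, 4.30 per Mb. Autosomes ranged from 11.7 per Mb on chromosome 3 to 24.0 on chromosome 11, and the Y chromosome had 3 peaks. Of the coding genes on the X 34.6% had a marked promoter, against 40.2% on chromosome 7, the lowest autosome, and 58.8% on chromosome 12, the highest. The X density was 6.72 in replicate 1 alone and 7.999 in replicate 2 alone. The lowest autosome, chromosome 3, was at 22.7 and 26.97 in the same lists.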

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

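The test of weak peaks, the separate tests of CpG content for epidermis and for the other lists, and the separate tests of PITX with CATATG and of NFY with T-box in low-repeat windows were chosen only after the results were seen.

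The replicated list held 5 peaks on sequences outside the 21 assembled chromosomes, a signal that no comparison used, and the replicate 1, replicate 2 and pooled lists held 6, 10 and 10.

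Epidermal, erythroid and leukocyte promoters were marked less often than other genes in the replicated list, while muscle and endothelial promoters were not past the threshold. Low CpG content as the whole cause over these 5 lists was argued against (25 of 101 promoters marked, 38.9 predicted from 10000 lists of like CpG content, percentile 0.01), and this rests on epidermis, with 4 of 24 marked and 12.4 predicted (percentile 0.01). For the muscle, endothelium, erythroid and leukocyte lists together 21 of 77 were marked and 26.6 predicted (percentile 3.8), so a deficit cannot be told apart from CpG content there. Peaks too weak to be replicated stay open: 25 of the 48 unmarked muscle, epidermis and endothelium promoters held a peak in another list, against 11 of 96 for genes of other organs (1-sided Fisher's exact p 2.73e-07), but the shares in those lists had been seen before, and only 1 of 13 erythroid and 3 of 15 leukocyte promoters did so. No biological explanation was tested, because the design has 1 group.

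The X chromosome had fewer peaks per Mb than every autosome. Repeat content as the whole cause was argued against, with 8.44 peaks per Mb of unmasked X sequence against 18.6 to 35.6 on the autosomes. Weaker signal stays open, because the median enrichment value at CpG-rich X promoters, 5.87, lay inside the autosomal range of 5.68 to 7.29 but the upper quartile, 10.5, lay below all autosomes (11.5 to 16.2), and promoters without a called peak could not enter either value. Gene content cannot be told apart from an effect on the X itself, because 76.3% (95% CI 67.8 to 83.04) of the CpG-rich X genes were marked and the lowest autosome, at 78.5%, lay inside that interval. The pools were of mixed sex, and whether the X of male or of female cells lowers the signal was not tested.

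PITX, NFY, T-box and CATATG sequences were less frequent at distal peaks than in nearby windows. In windows with at most 20% repeat bases 2 of the 4 motifs, NFY and T-box, kept an odds ratio under 1 past the threshold, with the lowest at 0.711. This argues against repeats in the background windows as the whole cause for NFY and T-box. For all 4 together, 2 of 4 decided nothing under the rule set before the test. For PITX and CATATG repeats stay open, as the lowest of their odds ratios in those windows was 0.924 and neither passed the threshold. No biological explanation was tested.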

How the results depend on the processing

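The settings "only peaks overlapped in both own lists", "genes with no other coding TSS within 2 kb" and "windows with at most 20% soft-masked bases" were chosen only after the results were seen, and the others before. Read depth was unknown, so its effect on weak peaks was not measured. Leaving out a replicate gave no value for overlap, rho or the replicated share, which need both, and ZNF143 had no finite odds ratio at promoters in low-repeat windows. The number of marked genes, the numbers of lists marked more and less often, the number of lists with more distal peaks and the number of motifs less frequent at distal peaks stayed within 1.5 times under every alternative run. Where a value below changed, the cause was not tested.

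Peaks shared of replicate 1 (55.2%) and of replicate 2 (43.8%) became 48.6% and 38.2% with overlap of at least 50% of the shorter peak, 31.3% and 25.8% with reciprocal overlap, 65.2% and 48.4% with q of at most 0.01, and 66.4% and 62.7% with equal numbers of top peaks. Rho (0.679) was 0.697 with overlap of the shorter peak and 0.715 with q of at most 0.01, and the replicated share (43.7%) 54.8% with q of at most 0.01. Without one replicate, the TSS share (38.3%) was 26.1% to 28.7%, HoxA coverage (44.4%) 40.4% to 43.8%, the widest domains kept 6 of 10 in both cases, lists with fewer distal peaks (2) 1 to 2, motifs more frequent at distal peaks (6) 10 in both cases, at promoters (6) 9 to 10, less frequent at promoters (5) 6 to 8, and X peaks per Mb (4.30) 6.72 to 7.999. Coverage of HoxB (1.65%) was 2.37% without replicate 1 and 2.77% in the pooled list, of HoxC (9.79%) 7.64% to 12.51%, and of HoxD (32.8%) 30.1% to 33.98% over the same lists and without replicate 2. The pooled list gave 25.2%, 46.8%, 5 of 10 domains, 10 distal motifs and 7.77 X peaks per Mb. The TSS share was 41.6% for only peaks overlapped in both own lists, 45.9% with a TSS window of 2.5 kb, 32.3% with 500 bp and 32.6% with TSSs of protein-coding transcripts only. Lists with fewer distal peaks fell to 1 with q of at most 0.01, assignment within 100 kb, a TSS window of 2.5 kb or no matching. Of the 10 widest domains, 5 stayed with a stitching distance of 3 kb, 3 with no stitching and 6 when ranked by enrichment times length. Distal motifs more frequent numbered 11 with windows of 500 bp, and promoter motifs less frequent 12 without GC matching.

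Directions that turned for marked promoters were, without replicate 1, HoxB and HoxC 57.9%, bone 55.6%, muscle 59.3%, epidermis 54.2% and endothelium 77.8%. Ridge signals turned without replicate 2 (62.5%), and ridge signals (56.2%) and endothelium (83.3%) in the pooled list. Of these only endothelium in the pooled list was past the threshold (adjusted p 0.0306). Without replicate 2, HoxB and HoxC (31.6%), bone (33.3%), muscle (33.3%), epidermis (29.2%) and endothelium (38.9%) did not turn, nor did ridge signals without replicate 1 (50%). For distal peaks per gene, against random lists, directions that turned were Schwann cells and melanoblasts 1.73 (q of at most 0.01), 1.27 (peaks in both own lists), 0.8 (100 kb), 1.8 (any distance) and 3.67 to 5.4 (the range without one replicate, whose ends need not both have turned), leukocytes 0.375 (both own lists), 0.438 (100 kb) and 0.875 (no matching), cardiomyocytes 0.812 (100 kb), HoxA and HoxD 0.1 (2.5 kb) and 0.5 (no matching), muscle 0.963 (2.5 kb), and without matching HoxB and HoxC 0.474, gut and pancreas 1.06 and housekeeping 0.731. For motifs, PITX had odds ratios of 1.04 (distal) and 1.30 (promoter) in low-repeat windows, and without GC matching at promoters MEF2 had 0.630 and the myogenic E-box 1.31. Of the values for single lists, motifs and clusters, 541 kept their direction and side of the threshold or their range, 21 fell short of the threshold, 8 newly passed it and 8 moved.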

Other observations

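The test of distal peaks at imprinted genes was chosen after several of the widest domains had been seen, and the values of noncoding genes and of the replicates' own lists were looked at after the other results.

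Promoters of long noncoding RNA genes were marked at 2146 of 10155 (21.1%), and at 840 of 7998 (10.5%) with no coding TSS within 2 kb. Among those named here, chosen after their values were seen, the highest enrichment values were at 2610037D02Rik (66.2), 1810026B05Rik (61.3) and Gm11266 (50.2). The peaks at 2610037D02Rik and Gm11266 also lay at the promoters of the coding genes Arid2 and Nfib. Malat1, an abundant nuclear RNA, had 43.9. Dnm3os (38.9, chr1:162217623–162225550), the precursor of microRNAs of skeletal growth, lies antisense to Dnm3, next to the widest domain.

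Promoters with a peak numbered 11139 in replicate 1 and 11809 in replicate 2, with 542 in replicate 1 only and 1212 in replicate 2 only. Epidermal genes had 7 promoters with a peak in replicate 1 and 13 in replicate 2, endothelial genes 7 and 14, and muscle genes 9 and 16. For none of the 22 lists was the split between promoters found in one replicate only past the threshold against other genes (smallest adjusted p 0.787, 2-sided Fisher's exact test). Such promoters were few per list. Muscle had 0 in replicate 1 only and 7 in replicate 2 only, and epidermis 0 and 6. Even these fully 1-sided splits gave unadjusted p of 0.107 and 0.186, so the test could not decide for them.

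Several of the widest domains lay at imprinted genes, among them Mest and H19, and a hypothesis is that some imprinted genes carry more distal H3K27ac in the limb than other genes. Over 28 imprinted genes, leaving out the 3 seen at the 40 widest domains, the mean was 4.43 distal peaks per gene, 2.54 times matched random lists (percentile 99.71, 2-sided permutation p 0.006). Genes were left out by name and not by locus. Igf2, on the chromosome of H19, stayed in with 7 distal peaks, and Klf14 and Copg2, on that of Mest, with 6 and 0. The test may therefore not be independent of the loci that raised the hypothesis. The median was 2, 13 of the 28 genes had none, and the 4 highest held 71 of the 124 peaks. Of these, Cdkn1c, an inhibitor of the cell cycle, had 23, Dlk1, an inhibitor of mesenchymal differentiation, 22, and Rtl1 and Slc38a4 13 each. Of the 28 promoters 20 were marked (71.4%, against 48.7% of other genes, odds ratio 2.64, Fisher's exact p 0.0217). Imprinted genes lie in clusters and share neighbouring peaks, so the 28 are not independent, and growth regulators active in many fetal tissues may give the same pattern.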
